A study of Rattus norvegicus with 18 samples.

How the data were processed

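The values are log2 ratios for 18 samples of whole rat lung, which the authors deposited as 1 table of 11994 rows. Per the labels and the series text, rats were exposed by nose only to diluted cigarette smoke or to conditioned fresh air for 1 h 2 times a day with a break of 30 min, on 5 days a week. Equal amounts of total RNA from 4 animals per group were pooled, amplified linearly and labelled by reverse transcription, smoke-exposed RNA with Cy5 and control RNA with Cy3, and each labelled sample was divided over 2 arrays of the PIQOR type. No dye swap is named. Scanner, background correction, spot filter and normalization are not given in the sources used here. The control source names show that the low-dose and high-dose samples of a combination of weeks and hours share 1 control pool, which makes 9 control pools.

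The unit and direction of the values were checked on the table. Of the 257 values under -1, 100% equal the log2 of a ratio rounded to 2 decimals, against 10.1% for the natural logarithm and 17.9% for log10. Each sample has a median between -0.01 and 0.01, so the deposited log2 ratios appear to have been centred by the authors. That a ratio stands for smoke over air, not the reverse, is taken from the channel labels and is not stated in the table. Of all cells 12.9% are empty, 153 rows hold no value and 7143 hold a value in every sample. A sample has a value in 78.8% (low dose, 2 weeks, 6 hours) to 94.7% (high dose, 13 weeks, 20 hours) of the rows. Signal intensities were not used here, so signal over background is unknown.

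Rows that repeat the values of another row of the same gene or probe were merged, which left 6036 distinct probes, 4780 with a gene symbol and 1256 without. A symbol was taken as the table gives it, and 9614 of 9658 rows with a symbol matched a gene identifier of the rat gene table for assembly GRCr8, used for names, synonyms and neighbours alone. A gene is the mean of its probes (133 of 4616 genes have more than 1), so probes that disagree are averaged. Genes with values at both doses in at least 6 of the 9 combinations were tested, 4016 in all, of which 3994 could be tested over hours and weeks. Probes without a symbol entered only the alternative with every probe on its own, and are also counted separately in the closing section.

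Tests used R 4.3.3 with limma 3.58.1 (lmFit and eBayes, default prior) and statmod 1.5.0, and all limma tests are two-sided. Against air, the mean of the 9 log2 ratios of a dose was tested against 0, without covariates. The dose comparison tested the 9 differences, high minus low, in which the shared control pool and a constant dye effect cancel. Hours and weeks were each tested by an F test on 9 means of the low-dose and high-dose sample of a control pool, with the other factor as a covariate, and by the 3 differences between levels. Whether the dose difference depends on hours or weeks was tested in the same way on the 9 differences. P values were adjusted by the Benjamini-Hochberg method within each test across genes, with a threshold of 0.05. Gene lists were tested by camera with a preset correlation of 0.01 and with an estimated correlation, and by fry, on the 3560 genes with a value in every sample, adjusted over the lists of 1 comparison. Python 3.11.15 with numpy 2.4.6 read the table and matplotlib 3.10.9 drew the figures.

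The tests, the named-gene rule, 24 gene lists and most alternatives were fixed before the data were examined. The rule names the 12 largest rises and 12 largest falls at the high dose among genes past the threshold with 1 sign in at least 8 of 9 samples, and the 6 and 6 at the low dose. It names up to 8 and 8 genes between the doses with 1 sign in at least 7 of 9 pairs, and up to 10 past the threshold with the smallest p over hours and over weeks. In each list it names up to 4 members past the threshold with the largest change at the high dose, or otherwise 2 as values, and for the clock, glucocorticoid and immediate early lists it goes by the range over hours. Cyp1a1, Cyp1b1, Nqo1, Hmox1, Bmal1, Per2, Dbp, Cxcl1, Ccl2, Mmp12, Sftpc and Scgb1a1 are named where tested. Other genes in the text, among them Csf1r, A2m, Fkbp5, Nr3c1, Cd4 and Ramp3, were chosen after their values were seen.

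The lists cover AhR targets, NRF2 and oxidative stress defence, glutathione S-transferases, other xenobiotic metabolism, chemokines and cytokines, acute phase and complement, interferon response and antigen presentation, and markers of macrophages, neutrophils and mast cells, lymphocytes, alveolar epithelium, airway epithelium, endothelium and smooth muscle, striated muscle, and blood. The others are extracellular matrix and proteases, cell cycle, p53 with DNA damage and apoptosis, heat shock and unfolded protein response, circadian clock, glucocorticoid-responsive genes, immediate early genes, lipid and cholesterol metabolism, and reference genes. Some members were found only through synonyms in the gene table, Gsta1 as Gsta2, Gstm3 as Gstm5, Cyp3a1 as Cyp3a23-3a1, Adh1 as Adh1c, Itgax as Itgad, Fcgr3a as Fcgr2a, Scd as Scd2, Ctgf as Ccn2 and Arntl as Bmal1, and Itgad and Fcgr2a may be other genes than the list meant.

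The tests were run on simulated data with the real genes, gaps and spreads and 200 changed genes. For changes of 0.5, 1 and 2 log2 units, 97.0%, 100% and 100% were recovered at the high dose with 14 unchanged genes called, 95.5%, 100% and 100% at the low dose with 9, and 95.5%, 100% and 100% between the doses with 7. Over hours the shares were 58.2%, 94.0% and 100% with 5 unchanged genes called, over weeks 64.2%, 88.1% and 100% with 2, for dose by hours 5.97%, 79.1% and 98.5% with 1, and for dose by weeks 4.55%, 56.7% and 97.0% with 4. The exact sign-flip permutation test recovered 0 of them at each size at the high dose, since its smallest p, 0.00391, is too large when few genes reach it. Of 50 lists of 15 genes, 10 were shifted by 0.3, and camera, camera with an estimated correlation and fry each recovered 10 of 10 and called 0 of the others. The simulated genes were drawn independently of each other. The simulation therefore does not test the preset correlation on lists whose members are correlated.

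Alternatives were arrays centred on their median or scaled to 1 spread, genes with a value in every sample, no filter on missing values (at least 3 combinations), every probe on its own, the robust prior, all 18 samples in 1 limma fit with control pools as a random block, the exact sign-flip permutation test over 512 sign patterns, weeks and hours as factors, a change of at least 1.5-fold, single doses, no covariate, and leaving out each combination or each duration. Leaving out each time after exposure, and the levels of each time and duration against air, were added after seeing the data. The overlap of the doses was set against 20 simulations without effect in which both doses shared control noise.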

Results

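Gene expression in whole rat lung after nose-only exposure to diluted cigarette smoke was read on 2-colour microarrays, as 18 log2 ratios of smoke-exposed over fresh-air lung. The smoke held 300 (low dose) or 600 (high dose) µg total particulate matter per litre. Exposure lasted 2, 7 or 13 weeks. The interval from the last exposure to tissue collection was 2, 6 or 20 hours, which gives 9 combinations of weeks and hours at each dose. Every condition had 1 sample, made from a pool of 4 exposed rats against a pool of 4 fresh-air rats, so no condition had replicates. The low-dose and high-dose samples of a combination shared 1 control pool. The series title names the kinetics of the expression changes as its subject. The comparisons ask what smoke changed at each dose, and how the change depended on dose, on the hours since exposure and on the weeks of exposure. Between 3919 and 4583 named genes had a value in a sample, and the number of arrays limits the precision. Errors are standard errors (SE) from limma fits across all genes. In what follows n is the number of samples or pairs. Values at a dose are means over the 9 combinations, also for genes whose level changes with time. The spread behind p against air and between the doses is that between combinations. It holds error between pools of animals and real change over time. For hours and weeks it is what remains after both factors.

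At the high dose, the largest named rises were those of Cyp1a1, Lcn2 and Aldh3a1. Cyp1a1, a cytochrome P450 that oxidises polycyclic aromatic hydrocarbons, rose 8.83-fold (log2 3.14 ± 0.67 SE, n = 9, above air in 8 of 9 samples, adjusted p = 0.0059). The aldehyde dehydrogenase Aldh3a1 rose 5.68-fold (2.51 ± 0.55). Lcn2, a siderophore-binding protein of innate defence, rose 6.28-fold (2.65 ± 0.16, in 9 of 9 samples, adjusted p = 3.84e-07). Complement C3 rose 3.45-fold (1.79 ± 0.16) and the neutrophil attractant Cxcl1 2.87-fold (1.52 ± 0.13). The quinone reductase Nqo1 rose 3.2-fold (1.68 ± 0.28) and the mitochondrial superoxide dismutase Sod2 2.25-fold (1.17 ± 0.13). The macrophage genes Lgals3 and Cd68 rose 2.42-fold (1.28 ± 0.10) and 2.18-fold (1.12 ± 0.10). The 12 named rises were completed by Fetub of the fetuin family (1.15 ± 0.09), the complement regulator C4bpa (1.12 ± 0.09) and the kininogen Kng2 (1.06 ± 0.08).

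The named falls at the high dose were smaller. The extracellular matrix protein Spon2 fell most, with a log2 ratio of -1.22 ± 0.12 (n = 9, below air in 9 of 9 samples, adjusted p = 1.72e-05). Adgre1, which encodes the macrophage surface protein F4/80, followed at -0.72 ± 0.06, Mal at -0.66 ± 0.08, the chemokine Cxcl14 at -0.64 ± 0.12 and Lrrn3 at -0.61 ± 0.08. Cd79b of the B cell receptor stood at -0.61 ± 0.10 and the cytotoxic granule protein Prf1 at -0.57 ± 0.11. The clock repressor Nr1d1 and the thyroid hormone receptor Thra, which lie overlapping on 1 chromosome, both stood at -0.57 ± 0.08. The collagen Col5a2 stood at -0.57 ± 0.09, the secreted Wnt inhibitor Wif1 at -0.56 ± 0.09 and the cytochrome P450 Cyp4b1 at -0.55 ± 0.06. All 12 falls were below air in at least 8 of 9 samples and past the threshold.

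Genes were also tested in lists by function, and some stand in several lists (Nqo1, Lcn2, Mt1, Mmp12, Lpl and Cd36 among others). Of 25 tested genes of oxidative stress defence (the NRF2 list), 16 rose and 0 fell over all genes, and 18 rose adjusted over the list alone. Among them were the metallothionein Mt1 (0.89 ± 0.08) and the haem oxygenase Hmox1 (0.73 ± 0.16). Camera gave adjusted p = 1.53e-09 for the list, with adjusted p = 0.073 with an estimated correlation. Of 7 tested targets or partners of the aryl hydrocarbon receptor (AhR), 4 rose on both counts, Cyp1a1, Aldh3a1, Nqo1 and the glucuronosyltransferase Ugt1a6 (0.49 ± 0.08). Cyp1b1 stood at 0.13 and did not pass. The AhR list had adjusted p = 0.000652, and adjusted p = 0.246 with an estimated correlation. Of 12 glutathione S-transferases, 6 rose and 1 fell over all genes and adjusted over the list alone, with Gstp1 at 0.74 ± 0.09. The transferase list had adjusted p = 0.0103, and adjusted p = 0.21 with an estimated correlation. Gsta2 stood at 0.37 ± 0.07 as the mean of 4 probes that ranged from -0.01 to 0.82, and Gstt2 and Gsto1 at 0.34 ± 0.09 and 0.33 ± 0.08. Of 23 other xenobiotic enzymes, 1 rose and 5 fell (2 and 5 adjusted over the list alone). Among the falls were Cyp2b12 (-0.39 ± 0.09), the flavin monooxygenase Fmo1 (-0.33 ± 0.06) and Cyp4a1 (-0.24 ± 0.05). This list as a whole did not pass (adjusted p = 0.159).

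Inflammatory and macrophage lists rose at the high dose while lymphocyte markers fell. Of 19 macrophage markers, 13 rose and 2 fell (14 and 2 adjusted over the list alone). The protease genes Ctsd and Mmp12 rose by 0.92 ± 0.09 and 0.81 ± 0.12, and Adgre1 and the growth factor receptor Csf1r (-0.19 ± 0.06) were the falls. The macrophage list had adjusted p = 2.21e-07, and adjusted p = 0.0563 with an estimated correlation. Of 15 acute phase and complement genes, 8 rose and 1 fell (10 and 1 adjusted over the list alone). The immunoglobulin transporter Pigr (0.90 ± 0.07) and haptoglobin Hp (0.86 ± 0.06) rose, and the fall was A2m (-0.19 ± 0.05). The acute phase list had adjusted p = 1.18e-06, and adjusted p = 0.054 with an estimated correlation. Of 12 chemokines and cytokines, 8 rose and 1 fell (9 and 1 adjusted over the list alone). Ccl3 stood at 1.00 ± 0.08, Csf2 at 0.71 ± 0.10 and Ccl2 at 0.28 ± 0.08, and the fall was Ccl5 (-0.51 ± 0.09). The chemokine list had adjusted p = 3.03e-05, and adjusted p = 0.054 with an estimated correlation (0.0497 on centred arrays). Of 13 lymphocyte markers, 10 fell and 0 rose on both counts, with a list median of -0.41. The T cell receptor chain Cd3g (-0.54 ± 0.09) and the granzyme Gzma (-0.52 ± 0.11) were among them. The lymphocyte list had adjusted p = 1.18e-06, and adjusted p = 0.0563 with an estimated correlation. Of 7 neutrophil and mast cell markers, 3 rose on both counts, S100a9 (1.43 ± 0.41, adjusted p = 0.0278), Fcgr2a (0.83 ± 0.12) and the chemokine receptor Cxcr2 (0.55 ± 0.11). Their list did not pass (adjusted p = 0.0847). The S100a9 value was -0.24 in the mean of the 2 week samples, and Fcgr2a was matched to the list only through a synonym of Fcgr3a. Outside the list, 2 further neutrophil genes, chosen after their values were seen, fell at the high dose. Retnlg stood at -0.43 ± 0.07 (below air in 9 of 9 samples, adjusted p = 0.00134) and Fcnb at -0.46 ± 0.14 (in 7 of 9, adjusted p = 0.0417). With both doses averaged, Fcnb depended on hours by the limma F test (adjusted p = 0.00528). It stood at -0.815 at 2 hours, 0.24 at 6 and -0.39 at 20 hours, and so lay above air at 6 hours.

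Further lists passed camera at the high dose with the preset correlation alone. Of 16 endothelial and smooth muscle genes, 1 rose and 4 fell (1 and 5 adjusted over the list alone). VE-cadherin Cdh5 stood at -0.35 ± 0.07, the growth factor Vegfa at -0.27 ± 0.06 and the receptor Tek at -0.24 ± 0.07, and the peptide Edn1 was the rise (0.37 ± 0.12). The endothelial list had adjusted p = 0.00792, and adjusted p = 0.125 with an estimated correlation. Of 22 extracellular matrix and protease genes, 2 rose and 5 fell (2 and 7 adjusted over the list alone). The rises were Mmp12 and the growth factor Ccn2 (0.51 ± 0.10), and the falls included the collagens Col1a1 (-0.53 ± 0.14) and Col3a1 (-0.50 ± 0.09). The matrix list had adjusted p = 0.0179, and adjusted p = 0.177 with an estimated correlation. Of 23 lipid genes, 6 rose on both counts. Among them were the fatty acid binding protein Fabp5 (0.90 ± 0.10), the lipase Lpl (0.65 ± 0.08), the cholesterol exporter Abcg1 (0.61 ± 0.10) and the scavenger receptor Cd36 (0.46 ± 0.10). The lipid list had adjusted p = 0.00639, and adjusted p = 0.0563 with an estimated correlation. Of 12 glucocorticoid-responsive genes, 5 rose and 1 fell (8 and 1 adjusted over the list alone). Lcn2, Mt1 and Fkbp5 (0.66 ± 0.12) were among the rises, and the fall was in the receptor Nr3c1 itself (-0.31 ± 0.07). The glucocorticoid list had adjusted p = 0.00205, and adjusted p = 0.0839 with an estimated correlation. Of 25 heat shock and unfolded protein response genes, 2 rose on both counts, Hspa1a (0.37 ± 0.07) and the stress factor Atf3 (0.35 ± 0.06). The heat shock list had adjusted p = 0.00663, and adjusted p = 0.395 with an estimated correlation. Of 11 reference genes, 4 rose on both counts, Gapdh (0.31 ± 0.06), Rplp0 (0.27 ± 0.06), Eef1a1 (0.21 ± 0.07) and Ppia (0.20 ± 0.05), with a list median of 0.11. The reference list had adjusted p = 0.0158, and adjusted p = 0.125 with an estimated correlation.

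The remaining lists did not pass camera at the high dose. Of 10 alveolar genes, 4 rose and 1 fell on both counts. The surfactant protein Sftpa1 stood at 0.54 ± 0.07, Sftpd at 0.50 ± 0.08, the protease Napsa at 0.35 ± 0.07 and the water channel Aqp5 at -0.29 ± 0.07 (adjusted p = 0.462). Of 10 interferon and antigen presentation genes, 3 rose and 3 fell on both counts. The class II genes RT1-Da (0.45 ± 0.05) and Cd74 (0.31 ± 0.07) rose where Irf7 (-0.43 ± 0.11) and the peptide transporter Tap1 (-0.30 ± 0.07) fell (adjusted p = 0.88). Of 16 immediate early genes, 5 rose on both counts (adjusted p = 0.182). Of 5 airway genes 1 rose, the cilia regulator Foxj1 (0.52 ± 0.11), or 2 adjusted over the list alone (adjusted p = 0.384). Of 21 p53 and apoptosis genes, 2 rose on both counts, Mdm2 (0.34 ± 0.07) and Bax (0.22 ± 0.05), and the list had adjusted p = 0.362. Of 20 cell cycle genes, the mitotic kinase Aurka rose (0.35 ± 0.07) and the inhibitor Cdkn2c fell (-0.22 ± 0.06) on both counts (adjusted p = 0.817). Of 10 clock genes, 1 fell on both counts, Nr1d1 (adjusted p = 0.523). Of 10 striated muscle markers and 3 blood markers, 0 passed limma on either count (adjusted p = 0.516 and 0.88 for the lists). Nppa stood at 0.37 ± 0.19, Mb at 0.15 ± 0.12, Hbb at -0.14 ± 0.10 and Pf4 at 0.11 ± 0.16.

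Of 4016 genes tested against fresh air at the high dose, 691 passed limma at an adjusted p under 0.05, 384 higher and 307 lower. An unadjusted p under 0.05 was found for 1245. The count was 322 by an exact sign-flip permutation test, 62 where a change of at least 1.5-fold was also asked for, 198 without the 7 week samples and 268 without the 13 week samples. In alternatives chosen after seeing the data it was 278 without the 2 hour and 398 without the 20 hour samples. All samples carried smoke in the same dye, so a constant dye effect of a gene adds to its value against air.

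At the low dose, Cyp1a1 and Aldh3a1 stood close to their high-dose levels. Cyp1a1 rose 8.98-fold (log2 3.17 ± 0.68, n = 9, above air in 7 of 9 samples, adjusted p = 0.0134), Aldh3a1 5.88-fold (2.56 ± 0.56) and Nqo1 2.66-fold (1.41 ± 0.25). Lcn2 rose 3.25-fold (1.70 ± 0.11, in 9 of 9 samples, adjusted p = 7.46e-07), C3 2.42-fold (1.28 ± 0.17) and Cxcl1 2.08-fold (1.05 ± 0.11). Spp1, the secreted phosphoprotein osteopontin, rose 2.26-fold (1.17 ± 0.20) at the low dose and stood at 0.49 ± 0.18 at the high dose (adjusted p = 0.0809). This difference did not pass (-0.68 ± 0.15, adjusted p = 0.0618). The falls were led by Spon2 (-1.05 ± 0.12), Lrrn3 (-0.49 ± 0.07), Cyp4b1 (-0.48 ± 0.06), the scavenger receptor Colec12 (-0.47 ± 0.06), the Wnt ligand Wnt5a (-0.46 ± 0.07) and Cxcl14 (-0.45 ± 0.09).

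At the low dose, lists of defence and inflammation shifted up, and so did the glucocorticoid and reference lists. Of 25 NRF2 genes, 9 rose (19 adjusted over the list alone), with adjusted p = 1.85e-12, and adjusted p = 0.056 with an estimated correlation. Of 19 macrophage markers, 10 rose and 1 fell (13 and 2 adjusted over the list alone). Of 12 chemokines 6 rose (8 adjusted over the list alone), and of 15 acute phase genes 7 rose on both counts. These 3 lists had adjusted p = 3.5e-09, 2.69e-06 and 2.76e-06, and also passed with an estimated correlation (adjusted p = 0.0397, 0.0118 and 0.0118). Of 12 glucocorticoid-responsive genes, 2 rose and 1 fell (5 and 1 adjusted over the list alone), and this list passed both ways as well. The list had adjusted p = 0.00211, and adjusted p = 0.0462 with an estimated correlation. Of 7 AhR genes, 4 rose on both counts, and of 12 glutathione S-transferases 4 rose and 1 fell (7 and 1 adjusted over the list alone). Both lists passed with the preset correlation (adjusted p = 6.46e-06 and 0.000339) and were lost at adjusted p = 0.173 and adjusted p = 0.177 with an estimated correlation. Of 22 matrix genes, 4 fell (2 rose and 8 fell adjusted over the list alone), with adjusted p = 0.00374, and adjusted p = 0.151 with an estimated correlation. Of 11 reference genes 2 rose (4 adjusted over the list alone) and of 7 neutrophil markers 2 on both counts. These 2 lists had adjusted p = 0.0146 and 0.0424, and adjusted p = 0.308 each with an estimated correlation. Of 13 lymphocyte markers, 1 fell on both counts, Cd4 (-0.28 ± 0.06), and the list did not pass (adjusted p = 0.0667).

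At the low dose 199 of 4016 genes passed limma, 141 higher and 58 lower, and 770 had an unadjusted p under 0.05. Of the 199, 163 were also called at the high dose, all in the same direction (120 up and 43 down), where independent lists of these sizes would share 13.5 and 4.43 genes. Shared control pools alone put low and high values on 1 side. The mean log2 ratios of the doses were correlated at 0.825 over genes, which are not independent replicates. In 20 simulations with shared controls and no effect the correlation was 0.492, and 0 genes were called at both doses by limma. With no gene changed, hardly any call is possible at either dose. Neither this 0 nor the independent lists thus show how far shared controls raise the overlap of 163. When low-dose and high-dose means were taken from different sets of 3 control pools, the correlation over genes averaged 0.622 (0.50 to 0.691 in 12 choices), against 0.681 with the same sets. A constant dye effect lies in every sample of both doses. It would also give such a correlation and calls in the same direction, so this check does not separate it from smoke. The count of 199 was 396 with all 18 samples in 1 fit, 0 by the exact sign-flip permutation test (where 138 genes reached its smallest two-sided p of 0.00391) and 22 with at least 1.5-fold asked for. It was 128, 50 and 33 without the 2, 7 and 13 week samples. Without the 13 week, 2 hour combination it was 123 and, in alternatives chosen after seeing the data, 48, 104 and 122 without the 2, 6 and 20 hour samples.

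Between the doses 7 single genes passed, 2 of them (Lcn2 and Hp) in the acute phase list and none in the AhR list. In the 9 pairs that shared a control pool, Lcn2 was higher at the high dose by 0.95 ± 0.14 (log2, n = 9, in 9 of 9 pairs, adjusted p = 0.00396). Fetub was higher by 0.59 ± 0.09, C4bpa by 0.58 ± 0.09, Kng2 by 0.57 ± 0.10, Hp by 0.55 ± 0.07 and Sod2 by 0.53 ± 0.10 (adjusted p = 0.0439), each in 9 of 9 pairs. Edn2, a vasoconstrictor peptide, was lower at the high dose, with a difference of -0.47 ± 0.09 (adjusted p = 0.0349), from log2 ratios of -0.48 ± 0.08 at the high and -0.01 ± 0.08 at the low dose. Cyp1a1 and Aldh3a1 had differences of -0.02 ± 0.08 and -0.05 ± 0.11 (adjusted p = 0.959 and 0.929), and Nqo1 one of 0.27 ± 0.07, above 0 in 8 of 9 pairs (adjusted p = 0.16). S100a9 stood 0.96 ± 0.21 higher at the high dose, and the differences of Cd79b and Cd3g were -0.48 ± 0.12 and -0.42 ± 0.09. These 3 did not pass (adjusted p = 0.063, 0.0889 and 0.0603).

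As a group, 13 lymphocyte markers were lower at the high than at the low dose, with a median of -0.33. By limma 0 were lower over all genes and 9 adjusted over the list alone, and the list had adjusted p = 4.03e-11, and adjusted p = 0.0271 with an estimated correlation. Acute phase and complement genes were higher (2 of 15 over all genes, 7 adjusted over the list alone). So were macrophage markers (0 of 19, and 9 higher with 1 lower adjusted over the list alone) and lipid genes (0 of 23, and 4 higher with 1 lower adjusted over the list alone). These 3 lists had adjusted p = 7.84e-08, 2.93e-06 and 0.000413, and each had adjusted p = 0.0483 with an estimated correlation. On arrays centred on their median these 3 had adjusted p = 0.0505 with an estimated correlation, past the threshold no longer. The NRF2 list (1 of 25 higher, 3 adjusted over the list alone), the glucocorticoid list (1 of 12 on both counts), and the cell cycle list (0 of 20, 1 adjusted over the list alone) passed with the preset correlation (adjusted p = 0.00165, 0.0134 and 0.0437). They had adjusted p = 0.3, adjusted p = 0.184 and adjusted p = 0.182 with an estimated correlation. The heat shock list was shifted up (adjusted p = 0.0203, and adjusted p = 0.498 with an estimated correlation) and the list of other xenobiotic enzymes down (adjusted p = 0.0061, and adjusted p = 0.268 with an estimated correlation), with 0 members past limma on either count.

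Of 4016 genes, 7 passed limma between the doses, 6 higher and 1 lower at the high dose, and 398 had an unadjusted p under 0.05. The count was 11 with arrays scaled to 1 spread, 24 among genes with a value in every sample, 0 by the exact sign-flip permutation test and 2 with at least 1.5-fold asked for. It was 0 without the 7 week and 4 without the 13 week samples and, in alternatives chosen after seeing the data, 0 without the 6 hour and 1 without the 20 hour samples. Leaving out single combinations gave from 4 (7 weeks with 2 or with 6 hours) to 20 genes (13 weeks, 2 hours), and 11 without 2 weeks, 20 hours.

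**Figure D1:**
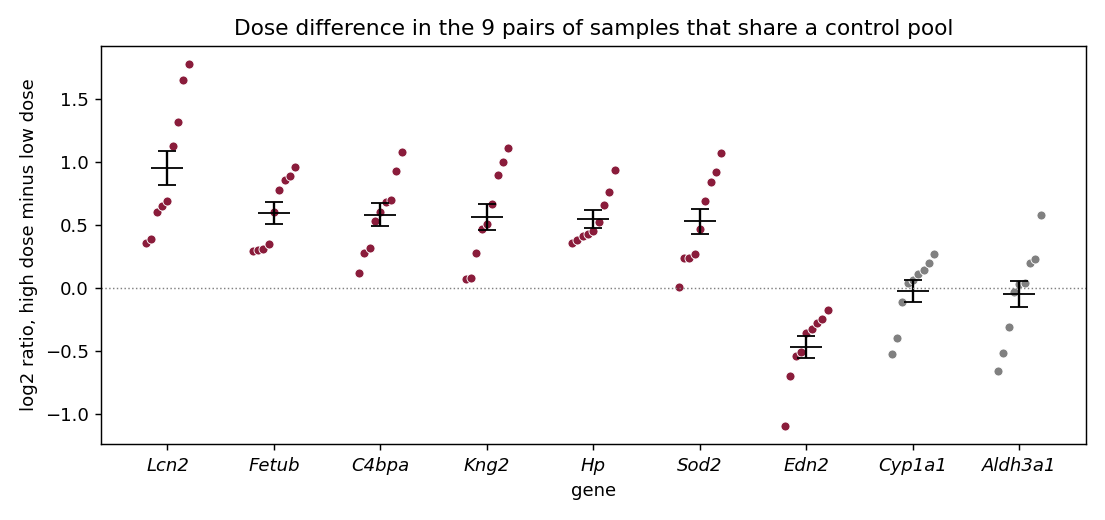
Difference in log2 ratio between the high and the low dose (vertical axis) for the 7 genes past the threshold and for Cyp1a1 and Aldh3a1 in grey (horizontal axis). Points are the 9 pairs of samples with a shared control pool in order of size, and bars are the mean ± SE. All 9 pairs lie above 0 for Lcn2, whose mean is 0.95, and below 0 for Edn2, whose mean is -0.47.

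The xenobiotic genes Aldh3a1, Cyp1a1 and Nqo1 differed between the hours since the last exposure. Aldh3a1 stood 40.1-fold above air at 2 hours (log2 5.33 ± 0.11, n = 3 control pools for each time), 3.87-fold at 6 hours (1.95) and at 0.32 at 20 hours (adjusted p = 1.19e-08 over hours). Cyp1a1 stood 53.4-fold above air at 2 hours (5.74 ± 0.24), 15.4-fold at 6 hours (3.94) and at -0.22 at 20 hours (adjusted p = 4.99e-06). Nqo1 went from 2.71 ± 0.07 to 1.62 and 0.30 (adjusted p = 5.14e-07). Hmox1 fell from 1.03 ± 0.07 at 2 hours to 0.38 and 0.23, and C3 from 2.28 ± 0.09 to 1.35 and 0.96. Ndrg4 stood at 1.72 ± 0.11, 0.27 and 0.05, Ms4a7 at 1.19 ± 0.09, 0.49 and -0.22, and Cxcl1 at 1.48 ± 0.09, 1.59 and 0.79 at 2, 6 and 20 hours, each past the threshold over hours.

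**Figure D2:**
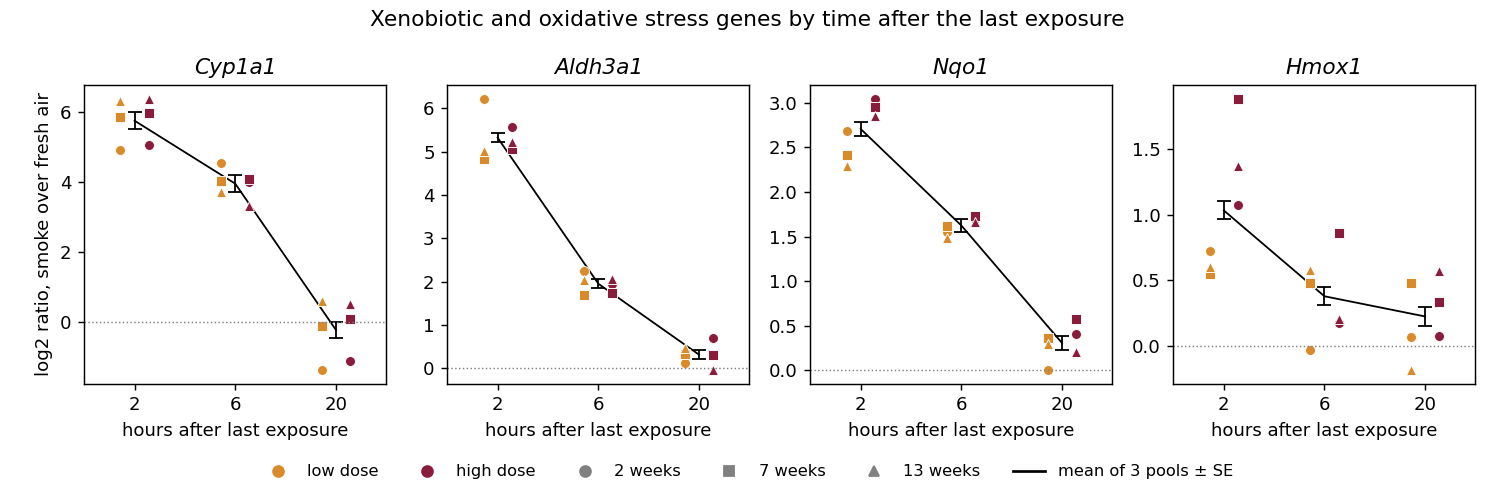
Log2 ratio of smoke over fresh air (vertical axis) at 2, 6 and 20 hours after the last exposure (horizontal axis) for Cyp1a1, Aldh3a1, Nqo1 and Hmox1. Points are single samples, coloured by dose and shaped by weeks of exposure, and the line joins means of 3 control pools ± SE. Samples of Cyp1a1 lie between 4.91 and 6.37 at 2 hours and between -1.36 and 0.62 at 20 hours.

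Of 10 tested clock genes, 5 passed over hours, and these 5 lay on both sides of air at different times. Bmal1, an activator of the circadian clock, stood at -1.20 ± 0.14 at 2 hours, 1.18 at 6 hours and -2.0 at 20 hours (adjusted p = 1.01e-05 over hours). Its repressor Nr1d2 went the opposite way, with 0.30 ± 0.12, -1.07 and 1.63 (adjusted p = 1.01e-05), as did the clock output factors Dbp (0.95 ± 0.18, -1.70 and 2.22, adjusted p = 1.04e-05) and Tef (0.45 ± 0.09, -0.32 and 0.85, adjusted p = 0.00185). Bhlhe40, a further clock repressor that was named after its values were seen, stood at 0.27 ± 0.09, -0.26 and 0.68 (adjusted p = 0.00915). The other 5 did not pass over hours, among them Nr1d1, which lay below air at all 3 times (-0.67 ± 0.08, -0.44 and -0.23, adjusted p = 0.132). From 6 to 20 hours, 4 of 10 clock genes rose and 1 fell, over all genes and adjusted over the list alone. The clock list had adjusted p = 0.00178, and adjusted p = 0.298 with an estimated correlation. From 2 to 20 hours 2 rose (5 rose and 2 fell adjusted over the list alone, adjusted p = 0.026, and adjusted p = 0.376 with an estimated correlation). The list was drawn up with knowledge of the study made on these samples, so its result is not independent evidence.

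**Figure D3:**
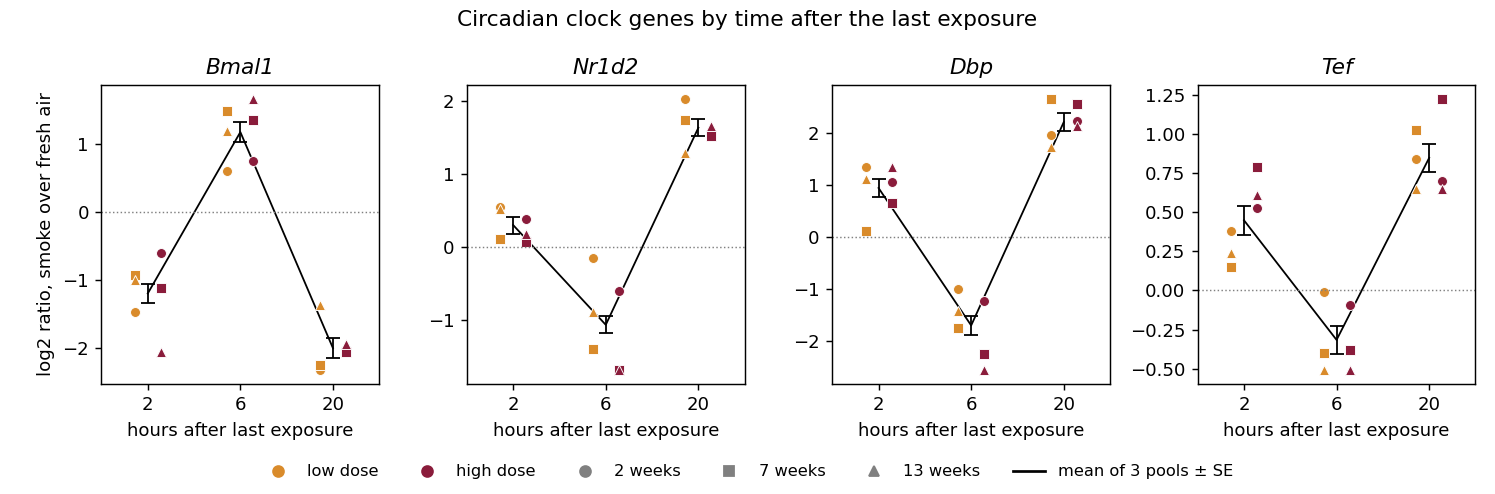
Log2 ratio of smoke over fresh air (vertical axis) at 2, 6 and 20 hours after the last exposure (horizontal axis) for the clock genes Bmal1, Nr1d2, Dbp and Tef. Points are single samples, coloured by dose and shaped by weeks of exposure, and the line joins means of 3 control pools ± SE. All samples of Bmal1 lie above air at 6 hours, between 0.60 and 1.67, and below it at 20 hours, between -2.32 and -1.36.

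Further lists shifted between the times with the preset correlation, and each of these calls was lost with an estimated one. S100a8, a calcium-binding protein abundant in neutrophils, stood at -0.68 ± 0.08 at 2 hours, 0.77 at 6 hours and 0.26 at 20 hours (adjusted p = 0.000156). From 2 to 6 hours 2 of 7 neutrophil markers rose on both counts, S100a8 and S100a9. The neutrophil list had adjusted p = 0.0184 for this step, and adjusted p = 0.353 with an estimated correlation. Of 25 heat shock and unfolded protein response genes, 3 rose and 1 fell from 2 to 6 hours (5 and 2 adjusted over the list alone, adjusted p = 0.00115, and adjusted p = 0.351 with an estimated correlation). In the same list 1 rose and 4 fell from 6 to 20 hours (1 and 7 adjusted over the list alone, adjusted p = 9.42e-05, and adjusted p = 0.298 with an estimated correlation). The glucocorticoid target Klf9 stood at 0.04 ± 0.09, -0.38 and 0.34 (adjusted p = 0.0353). Its list passed from 6 to 20 hours (1 of 12 rose, 3 rose and 1 fell adjusted over the list alone, adjusted p = 0.0479, and adjusted p = 0.298 with an estimated correlation). Of 16 immediate early genes, 1 fell from 2 to 6 hours (3 adjusted over the list alone, adjusted p = 0.00471, and adjusted p = 0.284 with an estimated correlation). That gene was Fosl1, which stood at 0.30 ± 0.07, -0.19 and 0.04 and did not pass the F test over hours (adjusted p = 0.0736). From 2 to 20 hours, 0 interferon and lymphocyte genes passed limma over all genes, with 3 of 10 and 2 of 13 higher adjusted over the list alone. These lists were shifted up (adjusted p = 0.000115 and 0.0155, and adjusted p = 0.356 and adjusted p = 0.475 with an estimated correlation). Of 20 cell cycle genes 0 passed on either count, and their list was shifted up (adjusted p = 0.0446, and adjusted p = 0.475 with an estimated correlation). From 6 to 20 hours, 1 of 23 other xenobiotic enzymes rose (4 adjusted over the list alone, adjusted p = 0.0183, and adjusted p = 0.298 with an estimated correlation). Lists of matrix, immediate early and interferon genes were also shifted up, with 0 members past limma over all genes and 4 higher with 1 lower, 0 and 1 higher adjusted over the list alone. They had adjusted p = 0.0409, 0.0479 and 0.0373, and adjusted p = 0.435, adjusted p = 0.298 and adjusted p = 0.337 with an estimated correlation.

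From 2 to 6 hours, 3 of 6 tested AhR genes fell (5 adjusted over the list alone, adjusted p = 5.46e-10, and adjusted p = 0.188 with an estimated correlation). In the same step 5 of 25 NRF2 genes fell (6 adjusted over the list alone, adjusted p = 0.00118, and adjusted p = 0.353 with an estimated correlation). From 6 to 20 hours 3 AhR genes fell on both counts (adjusted p = 1.05e-06, and adjusted p = 0.298 with an estimated correlation). From 2 to 20 hours, 3 AhR genes fell (6 adjusted over the list alone, adjusted p = 2.86e-17, and adjusted p = 0.0685 with an estimated correlation). In that time 5 of 25 NRF2 genes fell (1 rose and 7 fell adjusted over the list alone, adjusted p = 4.17e-06, and adjusted p = 0.376 with an estimated correlation). Of 3994 genes, 65 passed the limma F test over hours and 653 had an unadjusted p under 0.05. Their level lay farthest from air at 2 hours in 28 genes above and 6 below, at 6 hours in 12 and 7, and at 20 hours in 7 and 5. Against air, with both doses averaged (fits chosen after seeing the data), 533 genes passed at 2 hours (323 higher), 205 at 6 hours (137 higher) and 242 at 20 hours (136 higher). The count of 65 was 149 with all 18 samples in 1 fit, and 32 and 18 from high-dose and low-dose samples alone. It was 29 without the 7 week, 6 hour combination and 35 without the 7 week, 20 hour combination.

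Across the weeks of exposure, RNA of the neutrophil genes S100a8 and S100a9 rose against air. The genes past the threshold over weeks were 5 in all, and 4 of 36 splits of weeks, the real one among them, gave as many. The other such splits (6, 7 and 11 genes) only exchanged 7 and 13 weeks and kept the 2 week samples together. They thus keep any difference between 2 weeks and later. Splits that mixed 2 week samples with later ones gave at most 2 genes. The splits are too few to exclude chance for the count of 5. S100a8 went from -0.81 ± 0.08 at 2 weeks to 0.19 at 7 and 0.96 at 13 weeks (n = 3 control pools for each duration, adjusted p = 0.000111), and S100a9 from -0.41 ± 0.13 to 1.16 and 2.12 (adjusted p = 0.000111). Lgals3 rose from 0.63 ± 0.07 to 1.37 and 1.27, Lcn2 from 1.62 ± 0.09 to 2.57 and 2.33, and the platelet factor Pf4 from -0.48 ± 0.09 to 0.21 and 0.40 (adjusted p = 0.0148, 0.0299 and 0.0315). Cyp1a1 stood at 2.67 ± 0.24, 3.31 and 3.48 and Aldh3a1 at 2.80 ± 0.11, 2.33 and 2.46, neither of which passed (adjusted p = 0.851 and 0.702).

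Of 7 neutrophil and mast cell markers, 2 rose from 2 to 13 weeks (4 rose and 1 fell adjusted over the list alone, adjusted p = 1.25e-08, and adjusted p = 0.184 with an estimated correlation). Of 19 macrophage markers, 1 rose from 2 to 7 weeks (6 adjusted over the list alone, adjusted p = 1.35e-06, and adjusted p = 0.0985 with an estimated correlation). From 2 to 13 weeks 1 of them rose as well (5 adjusted over the list alone, adjusted p = 1.01e-05, and adjusted p = 0.141 with an estimated correlation). Of 25 NRF2 genes, 0 passed limma over all genes from 2 to 7 or to 13 weeks, with 4 and 3 higher adjusted over the list alone. Their list had adjusted p = 0.00111 and 0.00215, and adjusted p = 0.343 and adjusted p = 0.374 with an estimated correlation. Of 13 lymphocyte markers, 0 passed limma from 2 to 7 weeks and 2 were lower adjusted over the list alone. The lymphocyte list had adjusted p = 0.0146 for this step, and adjusted p = 0.343 with an estimated correlation. Of 3 blood markers, 0 passed from 2 to 7 weeks and 1, Pf4, rose to 13 weeks (Pf4 in both steps adjusted over the list alone). The blood list was shifted up in both steps (adjusted p = 0.0265 and 0.0104, and adjusted p = 0.236 and adjusted p = 0.221 with an estimated correlation).

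Other lists shifted over the weeks with the preset correlation alone. From 2 to 7 weeks 2 of 7 neutrophil markers rose (3 adjusted over the list alone), and from 7 to 13 weeks 0 did (2 adjusted over the list alone). That list had adjusted p = 3.21e-06 and 0.00243, and adjusted p = 0.232 and adjusted p = 0.822 with an estimated correlation. Of 12 chemokines, 0 passed to 7 weeks and 1 rose to 13 weeks (3 higher and 1 lower, then 1 higher, adjusted over the list alone). They had adjusted p = 0.0201 and 0.0104, and adjusted p = 0.232 and adjusted p = 0.221 with an estimated correlation. Of 15 acute phase genes, 1 rose to 7 weeks (3 higher and 1 lower adjusted over the list alone, adjusted p = 0.0426, and adjusted p = 0.236 with an estimated correlation). By limma 0 genes passed over all genes in the heat shock, interferon, reference and endothelial lists in either step from 2 weeks, and 1 heat shock gene adjusted over the list alone, to 7 weeks. The first 3 lists were shifted up and the endothelial list down. To 7 weeks they had adjusted p = 0.000195, 0.0284, 0.0417 and 0.0265, and adjusted p = 0.232, adjusted p = 0.343, adjusted p = 0.343 and adjusted p = 0.232 with an estimated correlation. To 13 weeks they had adjusted p = 0.029, 0.0104, 0.0205 and 0.0205, and adjusted p = 0.374, adjusted p = 0.286, adjusted p = 0.337 and adjusted p = 0.221 with an estimated correlation. The clock list was shifted down to 13 weeks with 0 genes past limma on either count (adjusted p = 0.0205, and adjusted p = 0.262 with an estimated correlation).

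Of 3994 genes, 5 passed the limma F test over weeks, 247 had an unadjusted p under 0.05, and 0 passed between 7 and 13 weeks (109 unadjusted). The 3 durations may each be a batch of animals and arrays, since no control pool spans them, so duration and batch cannot be told apart. The count was 3 with arrays scaled to 1 spread, 2 and 1 from high-dose and low-dose samples alone, and 2 without hours as a covariate. It was 2 without the 2 week, 2 hour or the 2 week, 20 hour combination, and 3 without the 2 week, 6 hour or the 7 week, 6 hour combination. Against air (fits chosen after seeing the data), 87 genes passed at 2 weeks, 312 at 7 weeks and 293 at 13 weeks.

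**Figure D4:**
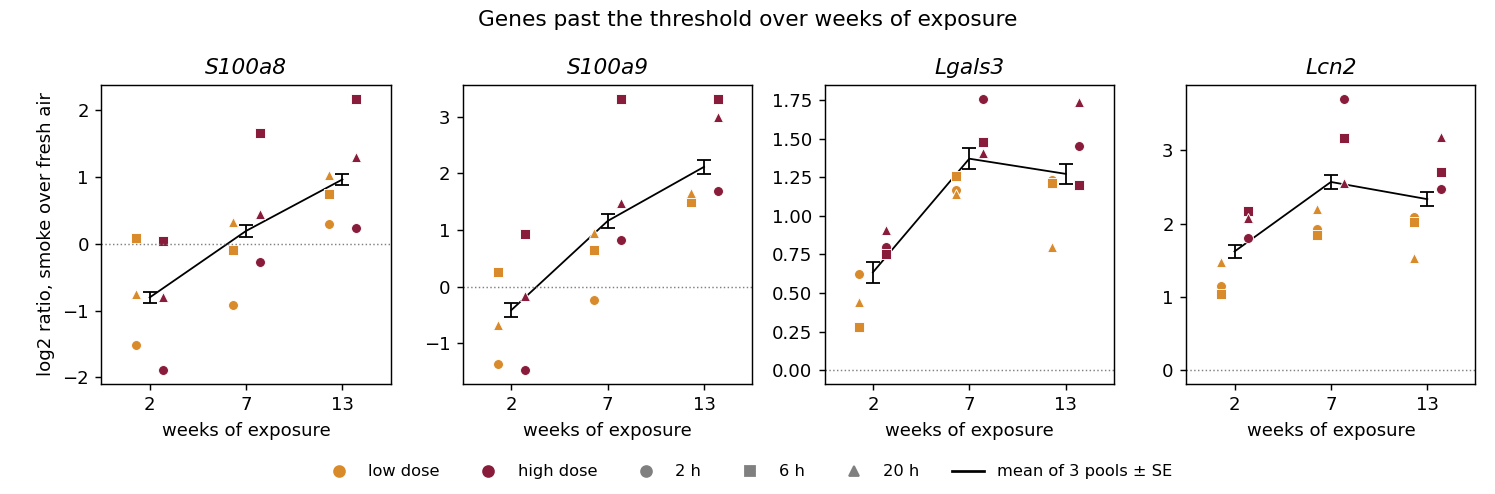
Log2 ratio of smoke over fresh air (vertical axis) after 2, 7 and 13 weeks of exposure (horizontal axis) for S100a8, S100a9, Lgals3 and Lcn2. Points are single samples, coloured by dose and shaped by hours after the last exposure, and the line joins means of 3 control pools ± SE. Samples of S100a9 lie between -1.47 and 0.93 at 2 weeks and between 1.5 and 3.32 at 13 weeks.

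No gene passed limma for a dose difference that depended on hours or on weeks, with 0 of 3994 in each test and 145 and 192 genes at an unadjusted p under 0.05. The smallest p over hours was that of Ramp3, a receptor partner of the adrenomedullin system, whose high minus low difference was 0.89 ± 0.13 at 2 hours, -0.06 at 6 hours and -0.15 at 20 hours (n = 3 pairs for each time, adjusted p = 0.451). On simulated data with 3994 genes these tests recovered 79.1% and 56.7% of interactions of 1 log2 unit, and 5.97% and 4.55% of those of 0.5.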

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

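The 3 tests on clock genes and the median over all 3 blood genes were chosen after the result was seen. All other tests here, and the splits of the samples, were planned.

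High and low dose differed, by a test of the difference itself in 9 pairs, in Lcn2 (0.95), Fetub (0.59), C4bpa (0.58), Kng2 (0.57), Hp (0.55), Sod2 (0.53) and Edn2 (-0.47, log2 high minus low). Times after exposure differed for Aldh3a1 (-5.01), Nqo1 (-2.41), Cyp1a1 (-5.96), Ndrg4 (-1.67), Ms4a7 (-1.41) and C3 (-1.32) from 2 to 20 hours, for S100a8 (1.44) from 2 to 6 hours, and for Nr1d2 (2.70), Bmal1 (-3.18) and Dbp (3.92) from 6 to 20 hours. Durations differed for S100a8 (1.77), S100a9 (2.53) and Pf4 (0.88) from 2 to 13 weeks and for Lgals3 (0.74) and Lcn2 (0.95) from 2 to 7 weeks. These are all 5 genes past the threshold over weeks, a count that 4 of 36 splits of weeks reached. Each of those splits kept the 2 week samples together, and the splits are too few to exclude chance for that count. Probes without a gene name, which entered only the alternative with every probe tested on its own, also passed limma: 153 of 979 at the high dose (58 higher and 95 lower), 20 at the low dose and 8 of 970 over hours.

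Genes changed at the low dose could in part carry a constant effect of the dye, since smoke always had the same dye. Such an effect is equal at both doses, but over the 199 genes called at the low dose the change was larger at the high dose by a mean of 0.10 (SD 0.06 over pairs), in 9 of 9 pairs (exact sign-flip p = 0.00391, two-sided, the smallest it can give). This argues against a dye effect as the whole cause, and a dye effect on single genes stays open. Of 100 sign patterns of the 9 samples, only the real 1 gave as many as 199 genes, and the highest other gave 15. Chance alone is thus unlikely to give this count, though 1 of 100 is the smallest share possible here. An effect of smoke is what the design set out to compare, and for most single genes it is not separated here from a dye effect. A constant dye effect cannot give a difference over hours. Of the genes called at either dose, 31 also passed over hours, Aldh3a1 and Nqo1 among them. For these genes a constant dye effect is argued against as the whole cause.

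Of 10 tested clock genes, 5 lay on opposite sides of air at different hours. With 1 aberrant control pool, a difference between 6 and 20 hours would show in 1 duration. Of all 10 clock genes, 4 differed by at least 1 log2 unit in each duration, and these 12 picks had the same sign in both other durations in 12 of 12 (size at least 0.68). The picks are the same 5 genes counted repeatedly, with Bmal1, Nr1d2 and Dbp picked in all 3 durations. They are thus 1 pattern seen in 3 durations, not 12 independent results. A constant dye effect keeps 1 side of air, but 12 of 12 picks lay on opposite sides at 6 and 20 hours in both other durations. Both are argued against for that step, in the picked genes. Collection or handling at another clock time than the controls may also give it, and the slope of high-dose on low-dose values, 1.07 (jackknife SE 0.09), does not separate this from a smoke effect already at its limit at the low dose. These explanations cannot be told apart, as clock times are not given in the sources used here.

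S100a8 and S100a9 rose with weeks of exposure. A rise of whole blood by 1 is argued against by the erythroid genes Hbb (0.04 ± 0.14) and Alas2 (0.15 ± 0.09, each with its own SE from the fit). Their median rise from 2 to 13 weeks was 0.093 (SE over genes 0.07), under the rise of 1 asked for. The platelet gene Pf4 rose by 0.88, and with it the median over all 3 blood genes was 0.15 (SE over genes 0.33), still under 1 by more than 2 SE. An SE over genes here treats 2 or 3 genes as replicates, so it decides little. From 2 to 7 weeks the 3 stood higher by 0.18 (Hbb), 0.02 (Alas2) and 0.69 (Pf4). As a list they were shifted up in both steps (adjusted p = 0.0265 and 0.0104), and the call was lost at adjusted p = 0.236 and adjusted p = 0.221 with an estimated correlation. Platelets or white cells without red cells stay open. More neutrophils may account for it, but the other neutrophil genes, Mpo (0.14), Cxcr2 (0.60) and Fcgr2a (0.69), had a median rise of 0.60 (SE 0.21), within 2 SE of the rise of 1 asked for. Retnlg (0.34) and Fcnb (0.08), neutrophil genes chosen after their values were seen, had smaller differences that did not pass. Both had means below air at the high dose, though Fcnb stood at 0.24 at 6 hours with both doses averaged. Genes chosen this way exclude nothing, so more neutrophils stay open. A batch shared by each duration stays open too, since 0 of 9 control pools hold samples of more than 1 duration, and batch and duration cannot be told apart. An effect of longer exposure itself, which the design names, is untested against these.

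Other splits of the samples were set against the remaining counts. At the high dose, 1 of 100 sign patterns, the real one, gave as many as 691 genes (highest other 171). Between the doses 1 of 100, the real one, gave as many as 7 (highest other 3). Chance alone is thus unlikely for these counts, though 1 of 100 is the smallest share possible here. The 7 genes between the doses also went to 0 without the 7 week or without the 6 hour samples. Over hours 1 of 36 splits, the real one, gave as many as 65 (highest other 6). Chance alone is unlikely there too, with 1 of 36 the smallest share possible. Over weeks 4 of 36 gave as many as 5 (highest other 11), each with the 2 week samples kept together. Splits that mixed these with later samples gave at most 2. The splits over weeks are too few to exclude chance for that count.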

How the results depend on the processing

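Leaving out each time after exposure was chosen after the results were seen, and all other alternatives were planned. The cause of a change was not tested except where fewer samples, fewer genes or a stricter rule give it by construction.

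With arrays centred on their median, the counts were 693 (high dose), 197 (low dose), 7 (between doses), 66 (hours) and 5 (weeks), all within 1.5 times. Scaled arrays gave 11 genes between doses and 3 over weeks, genes with a value in every sample gave 24 between doses, and the fit of all 18 samples gave 396 at the low dose and 149 over hours. The exact sign-flip permutation test gave 322, 0 and 0 genes at the high dose, low dose and between doses. Its smallest p was reached by 322, 138 and 38 genes. At the high dose these are the 322 called. At the low dose and between doses, as in the simulation, too few genes reached that p to pass. The 0 there says little about stability. With at least 1.5-fold asked for, 62, 22 and 2 remained. The high dose gave 198 without 7 weeks, 268 without 13 weeks, 278 without 2 hours and 398 without 20 hours. The low dose gave 128, 50 and 33 without 2, 7 and 13 weeks, and 48, 104 and 122 without 2, 6 and 20 hours. Between doses the count was 0 without 7 weeks or without 6 hours, 4 (3 of the 7 among them) without 13 weeks and 1 without 20 hours. Over hours, high-dose samples alone gave 32 and low-dose samples alone 18, and over weeks 2 and 1, with 2 without the covariate. The 0 genes of the dose by time tests by limma stayed 0 in both alternatives (145 and 192 unadjusted). Of 216 list tests, 73 passed with the preset correlation, 73 on centred arrays, 8 with an estimated correlation (6 on centred arrays, 5 of them shared) and 42 by fry.

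Leaving out 1 combination gave 498 to 679 genes at the high dose, 123 (without 13 weeks, 2 hours) to 193 at the low dose, 4 (without 7 weeks with 2 or 6 hours) to 20 (without 13 weeks, 2 hours) between doses, with 11 without 2 weeks, 20 hours. Over hours it gave 29 (without 7 weeks, 6 hours) to 68, with 35 without 7 weeks, 20 hours, and over weeks 2 (without 2 weeks with 2 or 20 hours) to 7, with 3 without 2 weeks, 6 hours or 7 weeks, 6 hours.

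Of 129 results on named genes, 2 that had passed the threshold turned direction. Gsta2 at the high dose was -0.012 on 1 of its 4 probes, and S100a9 was -0.24 in the mean of the 2 week samples. Results that had not passed changed sign without the 7 week (1), 13 week (1), 2 hour (1) and 20 hour (2) samples. Over the omissions of 1 combination, 1087 comparisons stayed on their side of the threshold, some never past it, 72 lost a call and 2 gained one, all in the same direction. With scaled arrays 123 stayed and 6 lost a call. Calls were also lost without the 2 week (9), 7 week (39), 13 week (30), 2 hour (27), 6 hour (21) and 20 hour (19) samples. The exact sign-flip permutation test lost 52, and asking for at least 1.5-fold lost 56. In the mean of the 2 week samples 12 moved by at least 1 SD. The intensities behind the ratios were not used here, so what weak signal limits is unknown.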

Other observations

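The genes in these paragraphs were chosen after their values were seen, and all values are log2 against air. Gclc, of glutathione synthesis, stood at 0.94 ± 0.08 at 2 hours, 0.28 at 6 and 0.12 at 20 hours (adjusted p = 0.00514 over hours), Gclm at 0.73 ± 0.09, 0.04 and 0.07 (adjusted p = 0.0299), the thioredoxin reductase Txnrd1 at 0.85 ± 0.08, 0.34 and 0.10 (adjusted p = 0.00915) and the glutathione hydrolase Ggt1 at 1.09 ± 0.07, 0.99 and 0.32 (adjusted p = 0.00302). Por, the electron donor of the cytochromes P450, stood at 0.82 ± 0.10, -0.26 and 0.31 (adjusted p = 0.00704). Of 4 single genes of the unfolded protein response, 3 chaperones were highest at 6 hours, Hspa5 at -0.29 ± 0.07, 0.43 and -0.16 (adjusted p = 0.00716), Hsp90b1 at -0.07 ± 0.07, 0.41 and -0.30 (adjusted p = 0.00774) and Pdia4 at -0.17 ± 0.07, 0.33 and -0.20 (adjusted p = 0.0372), and Herpud1 went the other way at 0.38 ± 0.07, -0.36 and 0.50 (adjusted p = 0.00201). The gap junction protein Gja1 (0.04 ± 0.13, 0.94 and 0.14) and the cytokine Il1b (0.14 ± 0.07, 0.76 and 0.39) were also highest at 6 hours (adjusted p = 0.0405 and 0.0181).

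Some changes passed at both doses and not over hours. The chemokine Ccl9 stood at 1.06 ± 0.09 at the high and 0.66 ± 0.10 at the low dose, complement factor Cfi at 1.01 ± 0.10 and 0.64 ± 0.08, and the lysosomal amidase Naaa at 0.97 ± 0.08 and 0.74 ± 0.09. The transcription factor Nfe2 stood at -0.46 ± 0.07 and -0.40 ± 0.08. Nr1d1 (-0.67 ± 0.08 at 2 hours, -0.44 at 6 and -0.23 at 20 hours, adjusted p = 0.132 over hours) and Thra (-0.55 ± 0.10, -0.49 and -0.38, adjusted p = 0.737) share 1061 bases on chromosome 10, and their array values do not show which of them was measured.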
